A study of Drosophila melanogaster with 8 samples.

How the data were processed

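RNA was measured by sequencing of mRNA in 8 libraries of Drosophila S2R+ cells transfected with Actin:dCas9-VPR and guide RNAs. Per the labels, 5 guides per gene were pooled, total RNA was extracted with TRIZOL, cleaned on a column with DNase treatment, and made into multiplexed Illumina mRNA libraries. The sample labels describe the control guides as directed to a luciferase reporter promoter, while the treatment protocol and the series design call them non-targeting. The deposited values are raw counts per gene symbol, 1 table per library, made by the authors with TopHat2 (version 2), Bowtie2, HTSeq and DESeq named in the labels without their order or role. The genome build, annotation, strand setting and count mode are not given in the sources used here.

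The tables list 14161 genes. Gene identifiers, coordinates and transcript lengths came from Ensembl 115 (BDGP6.54) by symbol: 10669 symbols were current, 3034 were older symbols matched to a current gene and 458 were not matched. Genes are named as in the deposited tables, except that qsm and DCTN3-p24 are given by their current symbols. Total counts ranged from 10752993 to 13351166. A count of 0 was given a floor of 3 counts over the group. In a single library 3 counts are 0.22 to 0.278 CPM, and the floor over both libraries of a group is lower than that. Ratios against 1 to 3 counts carry a counting interval at a confidence level of 95%.

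Differences were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: filterByExpr with a minimum count of 10 (8029 genes tested, 6132 left out, at least 99.94% of the counts kept), TMM factors (0.983 to 1.02), a robust quasi-likelihood fit of all 8 libraries on 4 groups (4 residual degrees of freedom, median prior 8.76, common biological coefficient of variation 0.079), F tests and Benjamini-Hochberg adjustment at 0.05 within each of 7 contrasts. Every adjusted p is from this fit unless DESeq2 1.42.0 is named. With 2 libraries per group, the spread was pooled over groups, and where leaving out a library left a group with 1, that library was assumed to vary like the others. p-values measure only the spread between the samples, which the series calls biological replicates. CPM are TMM-normalised. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

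Lists fixed before the data were examined, 19 in all with 416 written members (1 not found), were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation, none of these calls held. The list of mitochondrially encoded genes was empty, since the tables hold 0 of them. The other lists are mesoderm genes with known Twist input, genes with known Snail repression, epithelial junction and polarity, basement membrane, integrins and matrix proteases, muscle differentiation, hemocyte markers, innate immune genes, heat shock and unfolded protein response, FGF and EGF receptor signalling, Notch pathway and E(spl) complex, JNK pathway and cell death, cell cycle, neuronal and glial markers, germline and ovarian soma markers, ecdysone response, Snail family and cofactors, and cytosolic ribosomal proteins. The ribosomal list was taken by symbol (RpL, RpS or RpLP followed by a digit, and sta), so a gene named only for its likeness to a ribosomal protein can be in it. twi and sna were left out of the lists. Some genes are in more than 1 list. Some genes and 1 of the lists are not reported here, and the counts of calls include them.

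The design, the tests, the lists, the settings to be varied and the rule for naming genes were also set before the data were examined. The rule names twi and sna, and for each comparison with control the 10 largest rises and 10 largest falls among genes that passed, had both activated libraries on the same side of both control libraries and a mean of at least 1 CPM; 5 and 5 for the other contrasts; up to 4 members with the smallest p from each list; and the neighbours of the targets. The settings varied were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, DESeq2 tests, glmTreat against a fold of 1.5, an FDR of 0.01, only the groups compared, and, for lists, an estimated correlation and fry. A window of 500 kb around the targets and a correction for transcript length (a lowess trend per library, span 0.3, on 7863 genes with a length, 97.9% of those tested) were chosen after seeing the data.

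The procedure was tested on simulated data of the same size, with 1 spread per gene shared by all groups. The larger distance between the control libraries was not simulated, so the shares below need not hold for the real comparisons with control. At simulated log2 changes of 0.5, 1, 2 and 4, the shares recovered were 60, 72, 92 and 100% for Twist guides, 58, 88, 88 and 98% for Snail guides, and 44, 88, 96 and 100% for both pools. False calls were 9.5, 9.8 and 7.3% of calls, above the nominal 5%. Of 10 simulated lists of 30 genes moved by 0.3, 10 were called, and of 10 unmoved lists none was called at preset or estimated correlation. The simulated genes varied independently, so these lists could not show false calls that come from correlation between genes. In the real libraries the estimated correlation was 0.686 for the ribosomal list with Twist guides. With a simulated length trend, 97.5% of changed genes were recovered with and without the correction, and false calls were 15 and 13. Neither a genome sequence nor the guide sequences were available, so GC content and guide off-targets were not analysed here.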

Results

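Messenger RNA was sequenced from S2R+ cells, a Drosophila line with features of blood cells, after transfection with dCas9-VPR, a Cas9 that does not cleave DNA joined to a transcriptional activator. Pools of 5 guide RNAs directed the activator to the region upstream of twi, of sna or of both genes, and the control guides were described by the sample labels as directed to a luciferase reporter promoter and by the treatment protocol and series design as non-targeting. twi encodes Twist, a bHLH transcription factor that specifies the mesoderm of the embryo, and sna encodes Snail, a zinc-finger transcription factor of the same tissue. The 8 libraries formed 4 groups of 2: control guides, Twist guides, Snail guides and both pools. Total counts were 10959405 and 10752993 in the control libraries, 13141804 and 13351166 with Twist guides, 10951721 and 12051135 with Snail guides, and 12219683 and 10926704 with both pools. Between 9990 and 10393 genes had at least 1 count in a library, and the 10 most abundant genes held 5.75 to 6.18% of the counts. The p-values of the gene tests measure the spread between the 2 libraries of a group, pooled over groups, and counting intervals and floors cover counting error only. Pooling treats the groups as equally variable, but the control libraries lay farther apart than the others, as described next. The p-values against control can therefore be too small, and those of contrasts without the control group too large.

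The control libraries lay farther apart than the libraries of any other group. The variance of their difference was 24.29 times that of counting, against 6.42 with Twist guides, 3.57 with Snail guides and 3.45 with both pools. Control replicate 1 lay nearer to the Snail libraries (7.2 and 6.66) than to the other control library, and control replicate 2 lay nearer to the Twist libraries (13.74 and 13.5) than to it. Control replicate 2 was farthest from the Snail libraries (28.27 and 35.81). The difference between the control libraries followed transcript length: genes with very long transcripts were higher in control replicate 2, among them dp (71382 bp; 38 and 210 CPM), shot (65.6 and 281 CPM) and Msp-300 (61.2 and 200 CPM). Across genes, which are not independent replicates, Spearman's correlation of the difference between replicates with transcript length was 0.34 in the control pair, -0.19 with Twist guides, 0.07 with Snail guides and -0.18 with both pools. Relative to the mean of all libraries, the correlation with transcript length was -0.29 and 0.26 in the control libraries, 0.29 and 0 with Twist guides, -0.33 and -0.24 with Snail guides, and 0.26 and 0.06 with both pools. The fold changes against control had a correlation across genes with length of 0.04 for Twist guides, -0.24 for Snail guides and 0.08 for both pools.

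**Figure D1:**
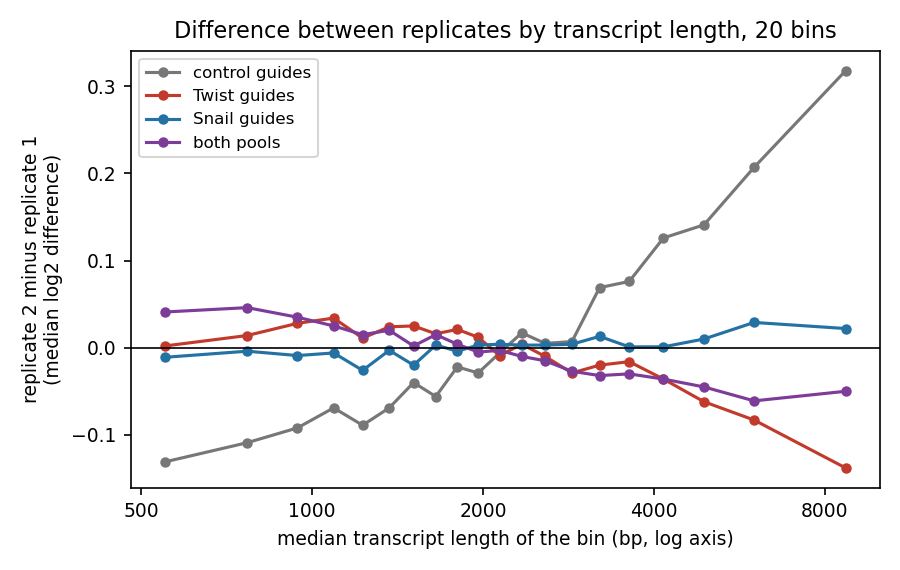
Median log2 difference between replicate 2 and replicate 1 of each group (vertical axis) in 20 bins of genes ordered by transcript length (horizontal axis, bp, log scale), each point a bin and each line a group. The control pair runs from -0.131 in the shortest bin to 0.318 in the longest.

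Both targeted genes rose with the guides aimed at them. twi (FBgn0003900, chromosome 2R, 22985374 to 23048325 in BDGP6.54) had 0 counts in the control and Snail libraries, 345 and 384 counts with Twist guides, and 164 and 137 counts with both pools. Its level was 27.3 ± 1.36 CPM with Twist guides and 13.2 ± 0.711 CPM with both pools (SD, n = 2), at least 197-fold and at least 95.4-fold higher than in control libraries, where the floor of 3 counts was taken over the group. sna (FBgn0003448, chromosome 2L, 15476593 to 15478260) had 2 counts in the control libraries and 1 count with Twist guides, and reached 99.4 ± 3.14 CPM with Snail guides and 123 ± 1.24 CPM with both pools. The ratios to control were 1080 (counting interval 298 to 8910) and 1330 (369 to 11000). With both pools, twi was lower than with Twist guides alone, at a log2 fold change of -1.05 ± 0.14 (SE; adjusted p = 0.0071), in 2 of 2 libraries. That call was lost without Twist replicate 2 (adjusted p = 0.12), replicate 1 of both pools (0.13) or replicate 2 of both pools (0.21). sna was 0.31 ± 0.10 higher with both pools than with Snail guides alone on the log2 scale (adjusted p = 0.14), and this difference passed the threshold without either control library (adjusted p = 0.0065 in each case).

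**Figure D2:**
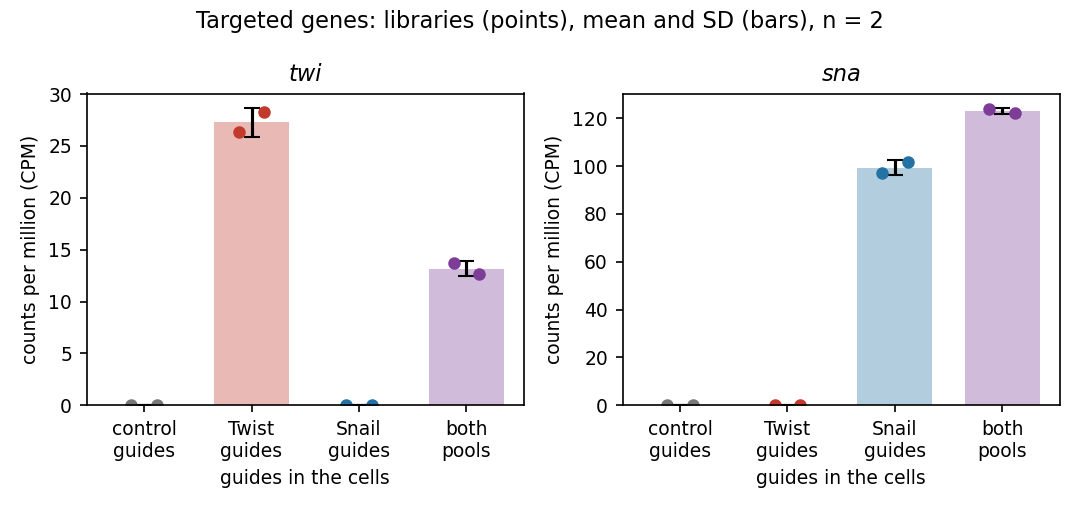
CPM (vertical axes, from 0) of twi and sna in the 4 groups of libraries (horizontal axes); points are libraries, bars are means and error bars are SD (n = 2). twi averaged 27.3 CPM with Twist guides and 13.2 CPM with both pools, and sna averaged 99.4 CPM with Snail guides and 123 CPM with both pools.

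Genes beside the targets were examined because the activator can also act on neighbours. CG9896, which lies within the annotated span of twi, had a log2 fold change of 0.92 ± 0.52 with Twist guides (adjusted p = 0.77) and 1.90 ± 0.49 with both pools (adjusted p = 0.14). With Snail guides, where twi had 0 counts, CG9896 stood at 0.76 ± 0.54 (adjusted p = 0.56), so its rise was not particular to Twist guides. It passed the threshold with both pools in DESeq2 (adjusted p = 0.00038). In edgeR it passed with Twist guides without Twist replicate 2 (1.48, adjusted p = 0.043), and with both pools without Twist replicate 1 (adjusted p = 0.0026) or Twist replicate 2 (adjusted p = 0.0023). CG42741, which overlaps twi on the opposite strand, had 0 counts in the control and Snail libraries, 15 with Twist guides (adjusted p = 0.12) and 26 with both pools (adjusted p = 0.02). The last call was lost without replicate 1 (adjusted p = 0.16) or replicate 2 (0.11) of both pools, and whether counting respected the strand is not given in the sources used here. DCTN3-p24, at 13095 bp from twi, had log2 fold changes of 0.10 and -0.01 with Twist guides and both pools, and lace, at 20867 bp from sna, had -0.01 and 0.17 with Snail guides and both pools; none of these passed the test, though lace passed it with Twist guides (0.24, adjusted p = 0.28) without control replicate 1 (0.28, adjusted p = 0.037). A window of 500 kb, chosen after seeing the data, held 76 tested genes around twi and 28 around sna. In it dnr1 (392 kb from twi) fell with Twist guides, CG4793 (445 kb from sna) rose with Twist guides by 1.65 ± 0.34 (adjusted p = 0.04) and with both pools by 1.75 ± 0.35 (adjusted p = 0.026), and esg (140 kb from sna) rose with Snail guides and with both pools. CG4793 was not called by DESeq2 with Twist guides (adjusted p = 0.16) or with both pools (0.053), and with both pools it was lost without replicate 1 (0.15) or 2 (0.22) of both pools. With Twist guides it was lost without control replicate 2 (0.059), Twist replicate 1 (0.27) or 2 (0.095), Snail replicate 1 (0.069) or 2 (0.07), and replicate 1 (0.1) or 2 (0.085) of both pools.

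Twist guides were compared with control guides to find the genes that change when twi is activated. dei (current symbol tx, chromosome 3R, 26440778 to 26448991), a bHLH transcription factor gene expressed in tendon cells, went from 1.52 ± 0.181 to 116 ± 25.8 CPM (SD, n = 2), a log2 rise of 6.24 ± 0.22 (SE; adjusted p = 1.1e-07). acj6, a POU-domain factor of olfactory neurons, and ect had 0 control counts and were at least 34.4-fold and at least 28.7-fold higher. PGRP-LB, an amidase that degrades bacterial peptidoglycan, rose by 6.09 ± 0.32, and CG9416 rose by 4.91 ± 0.65. CCKLR-17D3, a cholecystokinin-like receptor, rose by 4.41 ± 0.39, and htl, the FGF receptor of the mesoderm, rose by 3.92 ± 0.23, from 1.24 to 19 CPM. nvy, a transcriptional co-repressor gene, rose by 3.64 ± 0.20, and alpha-Est1, a carboxylesterase gene, rose by 3.46 ± 0.50. The falls were smaller. Cp1 (current symbol CtsL1), a cathepsin L, fell from 3590 ± 410 to 2130 ± 177 CPM (log2 -0.75 ± 0.10, adjusted p = 0.0012). CG6912 (-0.62), CG11899 (-0.60), Chit (current symbol Idgf6, -0.57), CG16721 (-0.50), dnr1 (-0.50), CG6805 (-0.45), the DNA ligase gene lig3 (-0.45) and Spn (-0.43) fell less.

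With Twist guides, 75 of 8029 tested genes passed the test, 66 higher and 9 lower, beside 665 at an unadjusted p under 0.05. DESeq2 called 72 genes (61 higher, 11 lower), of which 58 were shared. The number was 329 without control replicate 1 (105 higher), 510 without control replicate 2 (366 higher), 40 without Twist replicate 1, 49 without Twist replicate 2 and 47 without replicate 1 of both pools. The 10 named rises passed in each of the 8 fits that left out a library. Of the 9 named falls, 9 were lost without Twist replicate 1, 8 without replicate 1 of both pools, 7 each without Twist replicate 2, Snail replicate 1, Snail replicate 2 or replicate 2 of both pools, and 1 without control replicate 1. DESeq2 did not call CG6912 (adjusted p = 0.17), CG11899 (0.073) or CG6805 (0.069), and CG6912 (0.058) and Spn (0.086) were not called after correction for transcript length. With library size alone, CG6912 (0.07) and CG6805 (0.065) were not called, and CG6912 was not called with a filter of 1 CPM (0.05).

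Among the gene lists, 3 were called with Twist guides. Of 25 tested genes of basement membrane, integrins and matrix proteases, 3 rose and 22 were not called (4 higher when adjusted over the list alone; list adjusted p = 4.9e-06, adjusted p = 0.097 with an estimated correlation). They were Mmp1, a matrix metalloprotease (1.23 ± 0.10), trol, the perlecan gene (1.81 ± 0.17), and if, an integrin alpha chain (1.39 ± 0.24). The call of if was lost without Twist replicate 2 (1.14, adjusted p = 0.14), and alphaPS4 (1.35, adjusted p = 0.086) passed without control replicate 2 (2.12, adjusted p = 0.0012). Of 15 mesoderm genes with known Twist input, 2 rose, htl and if (2 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.00048, adjusted p = 0.097 with an estimated correlation). T48 stood at 0.26 and fog at -0.31 (adjusted p = 0.33; 0.0026 without control replicate 1). Of 10 innate immune genes, PGRP-LB alone rose (2 higher when adjusted over the list alone; list adjusted p = 0.00036, adjusted p = 0.097 with an estimated correlation), and pirk stood at 0.35 (adjusted p = 0.31; 0.015 without control replicate 1) and Dif passed only without control replicate 2 (0.59, adjusted p = 0.02). Without control replicate 1, the mesoderm list (adjusted p = 0.29) and the immune list (0.18) were no longer called.

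In lists that were not called with Twist guides, single members rose: argos, a secreted EGF receptor antagonist (0.55 ± 0.10), Nrg, the neuroglian gene (0.45 ± 0.09), and kon, which muscles need to reach their attachment sites (1.78 ± 0.35). None of these 3 calls held in every fit with a library left out, and Nrg was not called with the replicate number as a block. argos was lost without Twist replicate 1 (adjusted p = 0.053) or 2 (0.22). Nrg was lost without Twist replicate 1 (0.28) or 2 (0.13), Snail replicate 1 (0.076) or 2 (0.078), and replicate 1 (0.094) or 2 (0.076) of both pools, and in DESeq2 (0.072). kon was lost without Twist replicate 1 (0.27), Snail replicate 1 (0.05) or 2 (0.051), and replicate 1 (0.081) or 2 (0.066) of both pools, and in DESeq2 (0.085). The 83 tested cytosolic ribosomal protein genes, whose transcripts are short, had a median of -0.02 with Twist guides (list adjusted p = 0.52). That list was called upward without control replicate 1 (adjusted p = 5.3e-06) and downward without control replicate 2 (4e-09), and its median relative to the mean of all libraries was 0.05 and -0.19 in the control libraries.

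Snail guides were compared with control guides to find the genes that change when sna is activated. qsm (an older lethal-allele symbol in the deposited counts; chromosome 2R, 20563034 to 20583591), which encodes a zona pellucida domain protein, rose from 0.46 ± 0.256 to 30 ± 1.87 CPM (SD, n = 2), a log2 rise of 5.99 ± 0.37 (SE; adjusted p = 2.2e-05). esg (chromosome 2L, 15333866 to 15336138), a member of the Snail gene family, rose by 5.36 ± 0.37, from 0.184 to 8.02 CPM. Both a ligand and the receptor of mesodermal FGF signalling rose: pyr by 4.30 ± 0.34 and htl by 2.70 ± 0.26. Idgf4, a chitinase-like growth factor, rose by 3.76 ± 0.25, and CG31808 rose by 3.45 ± 0.50. Ggamma30A, a G protein gamma subunit, rose by 1.88 ± 0.28, if by 1.36 ± 0.24, and Ama, an immunoglobulin-domain adhesion gene, by 1.28 ± 0.21. The falls were in CG8547 (-0.64), CG33926 (-0.63), Cp1 (-0.59), CG6805 (-0.59), tmod, which encodes the actin-capping tropomodulin (-0.58), CG3860 (-0.56), Spn (-0.55) and CG5118 (-0.46). Cp1 went from 3590 to 2380 CPM (adjusted p = 0.025). Spn was not called after correction for transcript length (-0.34, adjusted p = 0.18), and tmod (adjusted p = 0.059) and CG5118 (0.055) were not called with library size alone.

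With Snail guides, 26 of 8029 genes passed, 18 higher and 8 lower, beside 1123 at an unadjusted p under 0.05; DESeq2 called 78 (30 higher, 48 lower), of which 24 were shared. The number was 1441 without control replicate 1 (504 higher), 65 without control replicate 2, 6 without Snail replicate 1, 8 without Snail replicate 2, 7 without replicate 1 of both pools and 10 without replicate 2 of both pools. Of the 10 named rises, 6 passed in all 8 fits that left out a library, and of the 8 named falls none did. Over the 18 named genes, 12 were lost without Snail replicate 1, 11 without Snail replicate 2, 12 without replicate 1 of both pools, 10 without replicate 2 of both pools, 5 without Twist replicate 1, 4 without Twist replicate 2, 2 without control replicate 2 and none without control replicate 1. The rises lost at least in part were CG31808, Ggamma30A, if and Ama.

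In lists of developmental genes, few members passed with Snail guides. Of 5 members of the Snail family and its cofactors, esg alone rose (1 higher when adjusted over the list alone; list adjusted p = 0.004, adjusted p = 0.41 with an estimated correlation); the median was -0.04 while the mean was 0.99 and the test pointed up. The list was not called without control replicate 1 (adjusted p = 0.2) or 2 (0.057). Of 10 genes with known Snail repression, pyr alone rose (1 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.007 upward, adjusted p = 0.41 with an estimated correlation), and brk, a transcriptional repressor gene, stood at -0.38 (adjusted p = 0.2; 0.0068 without control replicate 1). ths, a second ligand of htl, stood at 1.86 (adjusted p = 0.3). Without control replicate 1 that list pointed down (adjusted p = 0.99). In 21 genes of FGF and EGF receptor signalling, pyr and htl rose (2 higher and 3 lower when adjusted over the list alone), and the list was not called (adjusted p = 0.071; 0.024 without Snail replicate 1; 0.0092 after length correction; median -0.06, mean 0.37, test upward).

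Other lists were called with Snail guides although none of their members passed. The 83 ribosomal protein genes had a median of 0.15 with 80 above 0 (0 called, 0 when adjusted over the list alone, 7 at an unadjusted p under 0.05, 0 by DESeq2; list adjusted p = 9.3e-08, adjusted p = 0.46 with an estimated correlation), with RpL21 at 0.28, RpS29 at 0.29 and RpL24-like at 0.21. Of 17 heat shock and unfolded protein response genes, 0 were called (1 higher when adjusted over the list alone, 5 unadjusted, 1 by DESeq2; list adjusted p = 0.004 upward, adjusted p = 0.41 with an estimated correlation), with crc at 0.39 and Xbp1 at 0.30. Of 10 hemocyte markers, 0 were called (2 lower when adjusted over the list alone, 3 unadjusted, 0 by DESeq2; list adjusted p = 0.0067 downward, adjusted p = 0.41 with an estimated correlation), with srp at -0.36 and drpr at -0.37. Of 29 epithelial junction genes, 0 were called (0 when adjusted over the list alone, 9 unadjusted, 1 by DESeq2; list adjusted p = 0.033 downward, adjusted p = 0.46 with an estimated correlation), with l(2)gl at -0.50 and alpha-Cat at -0.42.

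The lists were also tested after correction for transcript length, a setting chosen after seeing the data. With it the ribosomal list had a median of 0.10 (adjusted p = 0.00021) and the epithelial list was not called (0.45). The corrected adjusted p was 0.0058 for heat shock, 0.0092 for hemocyte markers, 0.0056 for Snail repression and 0.0035 for the Snail family. With an estimated correlation none of these passed after correction: the adjusted p was 0.56 for the ribosomal list, 0.29 for heat shock and Snail repression, and 0.24 for hemocyte markers and the Snail family. The same correction added calls, both upward, for the FGF and EGF list and for the 13 neuronal and glial markers (0.13 before correction; adjusted p = 0.0092 in each list after it, 0.24 with an estimated correlation). The neuronal list also passed without Snail replicate 2 (0.017). Without control replicate 2, the ribosomal (adjusted p = 0.29), hemocyte (0.21) and epithelial (0.58) lists were not called. Without control replicate 1 the heat shock list was not called (0.13), and without Snail replicate 1 the epithelial list was not called (0.06). Without control replicate 1, members of each list passed, among them RpL21 (0.41), RpS29 (0.44), RpL24-like (0.27), crc (0.45), Xbp1 (0.43), srp (-0.46), drpr (-0.45), l(2)gl (-0.71) and alpha-Cat (-0.62).

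Both pools were compared with control guides to find the genes that change when twi and sna are activated together. esg rose by 6.06 ± 0.34 (SE; adjusted p = 4.4e-07), from 0.184 ± 0.002 to 13 ± 0.643 CPM (SD, n = 2). qsm rose by 5.51 ± 0.38, dei by 5.45 ± 0.22, PGRP-LB by 5.20 ± 0.35, CCKLR-17D3 by 4.01 ± 0.40 and htl by 3.88 ± 0.23. acj6 was at least 16.8-fold and ect at least 9.5-fold higher than in the control libraries, which had 0 counts. Falls were in the lysosomal mannosidase gene CG6206 (-1.12 ± 0.25), BM-40-SPARC, a collagen-binding glycoprotein of basement membranes (-0.95 ± 0.16), CG3091 (-0.93), CG6805 (-0.86 ± 0.10, adjusted p = 0.00053) and Cp1 (-0.72). CG3961 (-0.66), CG33926 (-0.64), CG14523, a neprilysin-like gene (-0.64), CG14629 (-0.63) and CG6126 (-0.60) also fell. BM-40-SPARC went from 683 ± 12.2 to 353 ± 39.3 CPM.

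With both pools, 126 of 8029 genes passed, 94 higher and 32 lower, beside 1327 at an unadjusted p under 0.05; DESeq2 called 164 (105 higher, 59 lower), of which 107 were shared. The number was 1152 without control replicate 1 (474 higher), 534 without control replicate 2, 63 without either Snail library, 22 without replicate 1 of both pools and 30 without replicate 2 of both pools. Of the 10 named rises, 8 passed in all 8 fits that left out a library, and of the 10 named falls, 1 did (CG6805). Over the 20 named genes, 11 were lost without replicate 1 of both pools, 9 without replicate 2 of both pools, 4 without Snail replicate 1, 4 without Snail replicate 2, 2 without control replicate 2, and 1 each without control replicate 1, Twist replicate 1 or Twist replicate 2. The rises lost were acj6 without replicate 1 of both pools (adjusted p = 0.057) and ect without replicate 1 (0.076) or 2 (0.055).

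With both pools, 10 lists were called. Of 13 neuronal and glial markers esg alone rose, while 11 were above 0 with a median of 0.25 (2 higher when adjusted over the list alone; list adjusted p = 8e-05, adjusted p = 0.3 with an estimated correlation), and mira, a neuroblast gene, stood at 1.18 (adjusted p = 0.13). Of 15 mesoderm genes htl and if rose (3 higher when adjusted over the list alone; list adjusted p = 0.0023, adjusted p = 0.3 with an estimated correlation), and Traf4 stood at 0.39 (adjusted p = 0.068). Of 21 FGF and EGF receptor genes htl and pyr rose (2 higher when adjusted over the list alone; list adjusted p = 0.0065, adjusted p = 0.3 with an estimated correlation). Of 25 basement membrane and integrin genes 4 rose and 2 fell (5 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.041 upward, adjusted p = 0.33 with an estimated correlation): trol (1.71 ± 0.18), Mmp1 (0.69 ± 0.11), if (1.41 ± 0.24) and CG6199 (0.45 ± 0.10) rose, and BM-40-SPARC and Pxn (-0.37 ± 0.09) fell. CG6199 was chosen after its values were seen. Of 10 innate immune genes PGRP-LB and pirk, a negative regulator of immune signalling (0.72 ± 0.11), rose (2 when adjusted over the list alone; list adjusted p = 0.043, adjusted p = 0.3 with an estimated correlation), with a list median of -0.09 and a mean of 0.25. In the list of the Snail family and its cofactors, esg was the only family member tested. It rose (1 of 5 genes, also when adjusted over the list alone). The list adjusted p was 0.0063 (0.3 with an estimated correlation), with a median of -0.09 and a mean of 1.03. Of 10 genes with known Snail repression pyr rose (4 higher when adjusted over the list alone; list adjusted p = 0.025 upward, adjusted p = 0.48 with an estimated correlation), and sog stood at 1.30 (adjusted p = 0.11).

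The ribosomal, cell cycle, and heat shock and unfolded protein response lists were called with both pools without a member that passed. The 83 ribosomal protein genes had a median of 0.15 (0 called, 0 when adjusted over the list alone, 9 unadjusted, 1 by DESeq2; list adjusted p = 2.7e-06, adjusted p = 0.53 with an estimated correlation). The 35 cell cycle genes had a median of -0.12 (0 called, 0 when adjusted over the list alone, 9 unadjusted, 0 by DESeq2; list adjusted p = 0.0012, adjusted p = 0.42 with an estimated correlation), with Mcm7 at -0.37 and CycA at -0.25. The 17 heat shock and unfolded protein response genes had a median of 0.13 (0 called, 4 higher when adjusted over the list alone, 5 unadjusted, 2 by DESeq2; list adjusted p = 0.045, adjusted p = 0.48 with an estimated correlation), with Hsc70-3 at 0.37, crc at 0.38 and Gp93 at 0.33. In lists that were not called, kon (2.36 ± 0.34) and Nrg (0.62 ± 0.09) rose, and Lac, a septate junction gene (-0.50 ± 0.09), and Pxn, also a hemocyte marker, fell (hemocyte list adjusted p = 0.14). After correction for transcript length, the basement membrane list was not called (adjusted p = 0.058), the corrected median of the ribosomal list was 0.17 (adjusted p = 1.6e-09, 0.37 with an estimated correlation) and that of cell cycle genes was -0.13 (adjusted p = 0.0019, 0.31 with an estimated correlation). The same correction added calls for the epithelial list (adjusted p = 0.034) and the hemocyte markers (0.04), both downward, and neither passed with an estimated correlation (0.26 each).

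Most list calls with both pools depended on control replicate 1. Without it the ribosomal and cell cycle lists were the only 2 of 10 kept, with adjusted p of 0.42 for basement membrane and for mesoderm genes, 0.4 for FGF and EGF, 0.97 for Snail repression, 0.63 for heat shock, 0.71 for immune genes, and 0.14 for neuronal markers and for the Snail family. Without control replicate 2 the ribosomal list (0.65) and the Snail family list (0.13) were lost. The basement membrane and heat shock lists were lost without Twist replicate 1 (0.066 each) or 2 (0.064 each), and the heat shock list without Snail replicate 1 or 2 (0.057 each) or replicate 2 of both pools (0.19). Without replicate 1 of both pools the basement membrane list (0.23) and the Snail repression list (0.08) were lost. Among named members, Mmp1 was lost without replicate 1 (adjusted p = 0.078) or 2 (0.086) of both pools, if without replicate 1 (0.17), pirk without replicate 2 (0.13) and Nrg without replicate 1 (0.09). CG6199 and Pxn were lost without Snail replicate 1 (0.1 and 0.11) or 2 (0.11 each) and without replicate 1 (0.26 and 0.14) or 2 (0.43 and 0.55) of both pools, and Pxn also without either Twist library (0.069 each). CG6199 was not called with library size alone (0.051), nor Pxn with a filter of 1 CPM (0.052), and neither was called with the replicate number as a block. Lac was lost without either library of both pools (0.26 and 0.13) and without either Snail library (0.06 each). Without control replicate 1, Mcm7 (-0.45), CycA (-0.30), Hsc70-3 (0.39), crc (0.43), Gp93 (0.43) and Traf4 (0.35) passed, and without control replicate 2 Hsc70-3 (0.35), crc (0.32), Traf4 (0.44) and sog (1.61) passed.

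**Figure D3:**
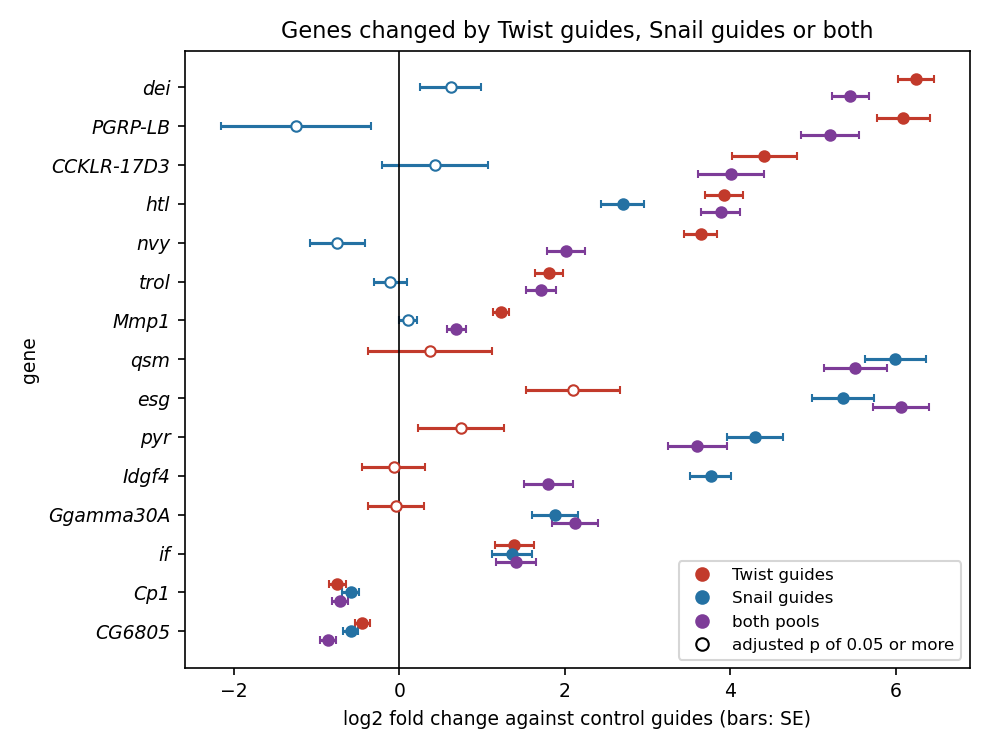
Log2 fold change against control guides (horizontal axis; bars are SE, 2 libraries per group) of 15 genes (vertical axis) with Twist guides, Snail guides or both pools; open points did not pass the test. dei stands at 6.24 and 5.45 with Twist guides and both pools, qsm at 5.99 and 5.51 with Snail guides and both pools, and Cp1 between -0.75 and -0.59 in all 3 comparisons.

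Adding Snail guides to Twist guides raised sna, qsm, esg and pyr, which Snail guides also raised alone, and lowered several genes that Twist guides had raised. sna was 3280 times higher (counting interval 589 to 130000, against 1 count). qsm was higher by 5.14 ± 0.34 (SE), esg by 3.97 ± 0.25, pyr by 2.85 ± 0.31 and CG32372 by 2.63 ± 0.41. btn, a homeobox gene, was lower by a log2 change of -1.91 ± 0.21 (adjusted p = 0.00079), from 17.6 ± 2.98 to 4.67 ± 0.464 CPM (SD, n = 2). CG9416 (-2.41), alpha-Est1 (-2.24), CG6231 (-1.97) and CG13707 (-1.86) were also lower. twi itself was lower, at 27.3 CPM with Twist guides and 13.2 CPM with both pools. An effect of Snail guides on these genes cannot be told apart from that of less twi. DESeq2 did not call alpha-Est1 (adjusted p = 0.074) or CG13707 (0.092). Of genes that each pool raised alone, htl stood at 19 and 18.4 CPM (-0.04 ± 0.15, adjusted p = 0.91) and if at 10.8 and 10.9 CPM (0.02 ± 0.20, adjusted p = 0.97), and neither was called. In this comparison 84 genes passed (40 higher, 44 lower; 1459 at an unadjusted p under 0.05; 158 by DESeq2), and after length correction 162 passed (70 higher). The number was 964 and 969 without control replicate 1 and 2, 199 and 9 without Twist replicate 1 and 2, 21 without either Snail library, and 7 and 9 without replicate 1 and 2 of both pools. Of the 11 named genes that passed, 6 were lost without Twist replicate 2, replicate 1 of both pools or replicate 2 of both pools, 3 without Snail replicate 1 or 2, and 1 without Twist replicate 1. sna, qsm, esg, pyr and btn were not lost in any of these fits.

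Adding Twist guides to Snail guides raised several genes that Twist guides also raised alone. twi was at least 102-fold higher. PGRP-LB was 94.4 times higher (counting interval 32 to 461, against 3 counts), ect 30.3 times (5.05 to 1240, against 1 count) and acj6 17.9 times (5.79 to 89.4, against 3 counts), and dei was higher by 4.83 ± 0.21 (SE; adjusted p = 1.7e-06). Idgf4 was lower by a log2 change of -1.96 ± 0.20, from 14.5 ± 1.46 to 3.72 ± 0.162 CPM (SD, n = 2; adjusted p = 0.00029). CG6206 (-1.18), CG6126 (-0.69), Idgf3, a further chitinase-like growth factor (-0.63), and grass, a serine protease of the Toll pathway (-0.59), were also lower. DESeq2 did not call grass (adjusted p = 0.069), and if, at 10.6 and 10.9 CPM (0.05 ± 0.21, adjusted p = 0.91), was not called. In this comparison 73 genes passed (57 higher, 16 lower; 1476 at an unadjusted p under 0.05; 183 by DESeq2). The share higher was 78.1%, and 64% of the 111 genes that passed after length correction; the fold changes had a correlation across genes of 0.29 with transcript length. The number was 1116 and 1123 without control replicate 1 and 2, 9 and 12 without Snail replicate 1 and 2, and 9 and 11 without replicate 1 and 2 of both pools. Of the 10 named genes, 6 were lost without Snail replicate 1 or either library of both pools, 5 without Snail replicate 2, and 2 without Twist replicate 1 or 2; twi, PGRP-LB, dei and Idgf4 were not lost.

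Twist guides and Snail guides were also compared directly, to show which genes differ between the activated factors. twi was at least 210-fold higher with Twist guides. PGRP-LB was 174 times (counting interval 59.3 to 847), ect 91.6 times (16.1 to 3650) and acj6 36.6 times higher (12.2 to 180), and dei was higher by 5.62 ± 0.20 (SE; adjusted p = 5.8e-08). With Snail guides qsm, Idgf4, pyr and esg were higher, at log2 differences of -5.62 ± 0.33, -3.83 ± 0.24, -3.55 ± 0.29 and -3.27 ± 0.26. In total 87 genes differed (65 higher with Twist guides, 22 lower; 956 at an unadjusted p under 0.05; 89 by DESeq2), and the fold changes had a correlation across genes of 0.31 with transcript length. The number was 837 and 842 without control replicate 1 and 2, 56 and 45 without Twist replicate 1 and 2, 38 and 42 without Snail replicate 1 and 2, and 52 without replicate 1 of both pools. All 10 named genes passed in each of those fits.

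A departure from additivity was tested as the log2 change with both pools minus the sum of the changes with each pool. htl was below the sum by -2.74 ± 0.31 (SE; adjusted p = 0.0059): it stood at 1.24 CPM in control libraries, 19 with Twist guides, 8.14 with Snail guides and 18.4 with both pools. btn (-2.37), pyd3, an enzyme gene of pyrimidine breakdown (-2.01), Pu, the GTP cyclohydrolase gene (-1.99), and sano (-1.19) were also below the sum. pyd3 stood at 3.69, 13.3, 5.74 and 5.11 CPM in the same order of groups. twi itself averaged 27.3 CPM with Twist guides and 13.2 CPM with both pools, and this difference cannot be separated from a departure from additivity. Cyp12e1, a cytochrome P450 gene (1.19), stj, a calcium channel subunit gene (0.98), CG7837 (0.90) and CG3860 (0.90) were above the sum. stj stood at 249, 204, 183 and 296 CPM. In total 14 genes passed (8 above, 6 below; 1174 at an unadjusted p under 0.05; 64 by DESeq2). After length correction 37 passed, and the share above the sum went from 57.1% to 37.8%; the estimates had a correlation across genes of 0.20 with transcript length. The number was 951 and 388 without control replicate 1 and 2, 1 without Twist replicate 2, Snail replicate 1 or replicate 1 of both pools, and 0 without Snail replicate 2 (790 at an unadjusted p under 0.05) or replicate 2 of both pools (691). None of the 10 genes picked by the naming rule passed in all 8 fits: htl was lost without Snail replicate 2 (adjusted p = 0.056) or replicate 2 of both pools (0.053), and the others were lost in more. Over the 10, 4 were lost without Twist replicate 1, 9 without Twist replicate 2, Snail replicate 1 or replicate 1 of both pools, and 10 without Snail replicate 2 or replicate 2 of both pools.

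Some genes changed with more than 1 kind of guide. htl, if and sano rose and Cp1, CG6805 and Spn fell with Twist guides and with Snail guides; sano was chosen after its values were seen and rose by 2.80 ± 0.11 and 0.70 ± 0.13. With Snail guides, sano was lost in DESeq2 (adjusted p = 0.051) and without control replicate 2 (0.071), Twist replicate 1 (0.078) or 2 (0.077), Snail replicate 1 (0.45) or 2 (0.29), and replicate 1 (0.1) or 2 (0.096) of both pools. Independent lists would share 0.15 rising and 0.009 falling genes. In 20 simulations with shared control libraries and no changed gene, the lists shared on average 0.3 and 0.45 genes. The simulated lists were not matched in length to the real ones, so simulated and real shared counts are not directly comparable. Twist guides and both pools shared 35 rising and 3 falling genes (simulated 0.3 and 0.3), and Snail guides and both pools shared 13 and 5 (simulated 0.3 and 0.3). The covariance of the fold changes exceeded that simulated from shared controls by 0.025 for Twist and Snail guides, 0.075 for Twist guides and both pools, and 0.055 for Snail guides and both pools. The simulated control libraries had the same spread as the other groups, unlike the real control pair. The simulations may therefore understate the covariance and the shared calls that shared controls alone give. The excess by itself cannot be attributed to a shared response. The correlations themselves were 0.366, 0.581 and 0.515, against simulated means of 0.52, 0.511 and 0.504. The effect of Twist guides without and with Snail guides, which rests on no shared library, correlated across 8029 genes at 0.31 (0.242 without twi and sna; 0.165 without Twist replicate 1). Of the 75 genes called with Twist guides, 64 had the same sign when Twist guides were added to Snail guides, with a median ratio of size of 0.47. The effect of Snail guides without and with Twist guides correlated at 0.211 (0.124 without twi and sna; 0.126 without control replicate 2), and 21 of 26 called genes had the same sign, with a median ratio of 0.52. Both sets of genes were chosen because they passed in the contrast that the ratio divides by. That choice alone lowers the ratios, so they do not measure how far an effect weakens beside the other pool.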

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

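The non-additive response was a planned test, and the tests on the distance between control libraries, the rise of esg and the lower twi were chosen only after those results were seen.

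The non-additive response drew attention because it tests whether the effect of Snail guides differs with and without Twist guides: 14 genes passed that test. The named genes above additivity were Cyp12e1 (1.19), stj (0.98), CG7837 (0.90) and CG3860 (0.90), and those below it were htl (-2.74), btn (-2.37), pyd3 (-2.01), Pu (-1.99) and sano (-1.19), all as log2 estimates. htl, Pu and sano were higher with Twist guides, Snail guides and both pools than in control libraries by their group means, and their combined level was at or below that with Twist guides alone. btn and pyd3 fell back with both pools towards control levels, from 17.6 to 4.67 CPM and from 13.3 to 5.11 CPM. twi was also lower with both pools, at 13.2 against 27.3 CPM, so less twi could contribute to these values, which was not tested. No group in this experiment had samples enough to test for single deviating libraries, since each had 2.

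The control libraries were farther apart than the 2 libraries of any other group. The difference in total counts was argued against, since their ratio was 1.02, against 1.02, 1.1 and 1.12 in the other pairs. Transcript length as the whole cause was argued against, because the robust SD of their difference was 0.236 after the length trend was removed, above the highest of the other pairs (0.15). Transcript length as part of the cause was consistent with the correlation of 0.34 across genes, the largest of the 4 pairs in size, and with the larger fall in SD, from 0.266. What else separates the libraries stays open, and because they belong to the same group, no biological explanation was tested.

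esg rose with Snail guides and lies 140 kb from sna. Activation spreading evenly to both sides of sna was argued against. Of 13 genes nearer to sna than esg, 12 were silent in control libraries. Together these held 2 counts in the Snail libraries, against 185 for esg. The test was widened to silent genes after the only nearer gene that could be tested, lace, was seen at -0.01 ± 0.07. However, lace lies on the other side of sna from esg, and how many of the 12 lie between sna and esg is not given here. Spreading towards esg alone was therefore not excluded. Reads of sna as the only source of the esg counts in both groups were argued against. The esg counts were 8.43 and 7.72% of sna counts with Snail guides and 10.2 and 11.1% with both pools. Fisher's exact test on counts (two-sided, p = 0.0054) covers counting error only. The related gene wor had 1 count in the Snail libraries. A part from sna reads was not excluded, since a fixed share of them beside a rise with Twist guides could also make the shares differ. Without Snail guides, at 0 and 1 sna counts, esg had 8 and 14 counts with Twist guides against 2 and 2 in the control libraries (log2 2.10 ± 0.57, adjusted p = 0.18; 0.015 adjusted over the Snail family list alone; 0.49 by DESeq2). A response of esg to Snail protein, a response that does not need it and off-target guides all stay open, and none was tested; guide sequences are not given in the sources used here.

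twi was lower with both pools than with Twist guides alone. An equal dilution of both guide pools was argued against only if twi and sna respond alike to guide dose, which was not measured. sna stood at a log2 change of 0.31 in the corresponding comparison, 7.9 combined SE above twi. A lower depth was argued against, because the ratio of twi counts was 0.413 (counting interval 0.36 to 0.473) and that of total counts was 0.874. Repression of twi when Snail is present, or unequal amounts of DNA from the pools, could each give this pattern, and neither was tested.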

How the results depend on the processing

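The 500 kb windows and the correction for transcript length were chosen after seeing the data; the other alternatives were planned. Counts are given in the order Twist guides, Snail guides and both pools against control, adding Snail guides, adding Twist guides, Twist against Snail guides, and the non-additive response. The cause was not tested unless stated.

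Without a filter on low counts, 128, 218, 353, 419, 436, 198 and 236 genes passed. By construction, glmTreat against a fold of 1.5 (31, 7, 19, 9, 10, 35 and 1) and an FDR under 0.01 (41, 7, 43, 14, 15, 49 and 1) gave fewer. DESeq2 moved the count to 78 for Snail guides, 158 for adding Snail guides, 183 for adding Twist guides and 64 for the non-additive response. With only the groups compared in the fit, 39, 6, 56, 712, 1546 and 714 genes passed; the non-additive response uses all groups, so this alternative gave no value for it. The control libraries, which have the largest spread, are absent from the last 3 of these fits. The first 3 keep the control pair and called fewer genes than the shared fit, though they also rest on fewer libraries. Correction for transcript length moved the count to 162 for adding Snail guides, 111 for adding Twist guides and 37 for the non-additive response. DESeq2 size factors, library size alone and a filter of 1 CPM left every count within 1.5 times the reported one.

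Leaving out each library in turn gave ranges of 40 to 510, 6 to 1441, 22 to 1152, 7 to 969, 9 to 1123, 38 to 842 and 0 to 951 genes, and the highest count in each range came without a control library. A fit without a control library no longer takes the distance between the control pair into its pooled spread; leaving out a library of another group gave 199 or fewer genes in each contrast. The targeted genes twi and sna kept their rises against control in all of these fits.

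The replicate block, with the replicate number of the labels as a block in the fit, gave 76, 35, 119, 98, 55, 87 and 18 genes. The deviations of replicates correlated across genes between groups at -0.148 to 0.142, so the numbers do not show a pairing of libraries.

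The correlation across genes of the Twist effect without and with Snail guides was 0.042 without a filter and 0.165 to 0.379 with each library left out; that of the Snail effect was 0.019 and 0.126 to 0.263. Shared calls at an FDR under 0.01 were 1 for Twist and Snail guides, 20 for Twist guides and both pools, and 6 for Snail guides and both pools, and DESeq2 shared 28 in the last pair. Within 500 kb, 2 genes were called near twi and 2 near sna, against 1 and 0 among the nearest genes, and the wider windows hold more genes.

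With an estimated correlation none of the 3, 7 and 10 list calls of Twist guides, Snail guides and both pools held, and with fry 3, 1 and 1 did. Library size alone and the replicate block kept all of them, and length correction kept 3, 6 and 9. Without control replicate 1, 1, 4 and 2 were kept, and the list of genes with known Snail repression reversed with Snail guides (adjusted p = 0.99, downward, at the upper end of 7.2e-05 to 0.99 over the libraries left out); without control replicate 2, 3, 2 and 8 were kept.

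At the present depth, simulated changes of 0.5 on the log2 scale were recovered in 60, 58 and 44% of cases in the 3 comparisons with control, so smaller effects are often missed. These shares come from a simulation without the larger spread of the control pair. Genes at a few counts, such as twi and sna in the control libraries, allow only bounds or wide counting intervals.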

Other observations

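The genes in the next paragraph were chosen after their values were seen, and their tests were planned for all genes.

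Further genes outside the naming rule passed the test. ash2, a subunit of histone methyltransferase complexes, rose with Twist guides from 82.3 ± 0.775 to 135 ± 8.85 CPM (SD, n = 2), a log2 rise of 0.71 ± 0.08, and SerT, the serotonin transporter gene, rose by 1.67 ± 0.24; both calls held in all fits that left out a library. With both pools the trehalose transporter gene Tret1-2 rose by 0.64 ± 0.09, the glycogen phosphorylase gene GlyP by 0.59 ± 0.10 and the phosphofructokinase gene Pfk by 0.54 ± 0.09. These 3 calls were lost without replicate 1 (adjusted p = 0.057, 0.11 and 0.076) or replicate 2 (0.082, 0.14 and 0.17) of both pools. With Snail guides the glutathione transferase gene GstD3 rose by 0.70 ± 0.08, and this call was lost without Snail replicate 1 (adjusted p = 0.061).

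Lists that were not called in any comparison with control were ecdysone response, germline and ovarian soma markers, JNK pathway and cell death, muscle differentiation, and the Notch pathway. Their adjusted p for Twist guides, Snail guides and both pools were 0.76, 0.077 and 0.93 for 16 ecdysone genes, 0.52, 0.41 and 0.34 for 14 germline genes, 0.33, 0.18 and 0.63 for 16 JNK genes, 0.52, 0.071 and 0.12 for 17 muscle genes, and 0.52, 0.51 and 0.93 for 11 Notch genes. Mmp1 rose in the JNK list with Twist guides and both pools, kon rose in the muscle list in the same comparisons, and edgeR called no other member (with Snail guides 0 in both lists, 3 JNK and 4 muscle genes at an unadjusted p under 0.05, and 1 and 0 by DESeq2). The muscle list was called downward with Snail guides without control replicate 1 (adjusted p = 0.009) and upward with both pools without control replicate 2 (0.046). fry called the JNK list upward with Twist guides (0.029) and downward with Snail guides (0.026). Among the ecdysone, germline and Notch genes, edgeR called 0 members. At an unadjusted p under 0.05 they numbered 2, 2 and 6 for ecdysone, 2, 1 and 3 for germline, and 1, 3 and 2 for Notch, and DESeq2 called 1 ecdysone gene with both pools.

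Lists called in some comparisons were not called in others. With Twist guides the adjusted p was 0.83 for cell cycle genes, 0.52 for epithelial and heat shock genes, 0.088 for FGF and EGF, 0.33 for Snail repression, 0.78 for hemocyte, 0.97 for neuronal and 0.55 for Snail family and cofactor genes. With Snail guides it was 0.43 for basement membrane, 0.51 for cell cycle, 0.3 for immune, 0.25 for mesoderm and 0.13 for neuronal genes, and with both pools 0.14 for epithelial and 0.14 for hemocyte genes. Leaving out control replicate 1 added the epithelial (0.0041) and hemocyte (0.036) lists with Twist guides and the epithelial (0.0028) and hemocyte (0.0028) lists with both pools, all downward. Leaving out control replicate 2 added Snail repression (0.0068) and heat shock (0.012) with Twist guides, upward, and leaving out Snail replicate 2 added neuronal markers with Snail guides (0.017).

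Median, mean and test differed in sign in several of the lists that were not called. With Twist guides the median was negative and the mean positive for ecdysone (-0.03 and 0.06), JNK (0.00 and 0.06), muscle (-0.07 and 0.22), neuronal (-0.02 and 0.18), cell cycle (0.00 and 0.02) and hemocyte genes (-0.06 and 0.00), and the test pointed down for ecdysone, neuronal and hemocyte genes. With Snail guides they were -0.10 and 0.10 for basement membrane, -0.04 and 0.17 for mesoderm, and -0.03 and 0.43 for neuronal genes, with the test upward, and for Notch genes both were 0.00 with the test downward. With both pools they were 0.05 and -0.05 for ecdysone genes with the test upward, -0.03 and 0.05 for JNK genes with the test upward, and 0.00 and -0.05 for Notch genes with the test downward.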
